A study of Arabidopsis thaliana with 2 samples.

How the data were processed

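Transcripts of Arabidopsis thaliana shoots were measured on 2 Agilent arrays of 60-base probes, each hybridised with 2 labelled samples. One was RNA of a Col-0 line (line 17) carrying an artificial microRNA against COX19-1 and COX19-2. The other was RNA of wild-type Col-0. Per the labels, the leaves came from plants grown for 10 days on 0.5x MS medium with 16 h of light and 8 h of dark at 23 °C, and 200 ng of total RNA per sample was labelled. The dyes were swapped: on array 1 the silenced RNA carried Cy5 and the control RNA Cy3, and on array 2 the silenced RNA carried Cy3. The labels give 2 biological replicates of each genotype but do not say whether these were separate plant cultures, so p-values measure only the spread between these samples, which may be technical. The labels conflict on 1 point: the control channel of array 1 is called replicate 1 in the title and description, while its source name carries the number 2. If both arrays held the same control RNA, the control would be 1 sample and its own spread would be missing from every test. Both arrays were on 1 slide and in 1 scan, so there was no batch to compare.

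Per the file headers, spots were read with Agilent Feature Extraction 10.7.3.1, and the deposited mean and background signals are spot intensity values on a linear scale with no normalization. Per the file headers, the processed intensity values were background-subtracted, detrended and dye-normalized by the scanner software. The deposited log10 ratios of red over green equal those of the processed signals and were not used in a test. Other deposited columns are flags of 0 or 1 for spots well above background, saturated or uneven, per the file headers. The authors also deposited 1 log2 ratio per probe and array for 43588 probes; the submitters' processing notes name limma, with no version, and the normalization behind these values is not given in the sources used here. Set against the scanner values, both columns run as silenced over control on about a log2 scale, with slopes of 1.15 and 1.17 and r = 0.954 and 0.950 across probes for values under 1 in size. In 1419 and 1327 values of size 1 or more the decimal point was lost. It was restored after the first digit, and 99.8% and 99.6% of the restored values had the sign of the scanner ratios. The column medians of the intact values were -0.00615 and -0.00721, and whether the authors centred them stays unknown. These values served as an alternative only.

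Signals were background-corrected with normexp (offset 50) and normalized within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Control spots and 40 and 7 outlier spots were left out, spots of a probe were averaged, and no spot was saturated. Each log2 ratio was turned to silenced over control by the dyes in the labels. As a check of the labels, all 10 spike-in sequences kept the sign of red over green on both arrays, while the ratios of genes turned (r = -0.906 before turning). Of 43603 probes, 34222 were matched to 1 locus by accession, 1214 by locus code and 600 by symbol, through a gene table of assembly TAIR10.1 used for names only; 475 named several loci and 7092 named none here. Probe coordinates are those of the array files, which name TAIR10. A gene's value was the mean of its probes that name 1 locus and were well above background on both arrays in the RNA of at least 1 genotype, which left 29007 probes and 20577 genes. Of these genes, 6414 had more than 1 such probe, and in 48 the probes differed in sign by more than 0.2 each way.

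Genes were tested with lmFit and eBayes in limma and adjusted by Benjamini-Hochberg at 0.05. The fit has 1 residual degree of freedom, and limma estimated infinite prior degrees of freedom, so each gene was judged against a common SD of 0.14 between arrays (SE of a mean 0.10) and not against its own spread. The adjusted p-values are therefore much smaller than 2 arrays alone could give, and some fall below what the software can represent. Gene lists with at least 3 tested members (27 of 28) were tested with camera, two-sided, at a preset inter-gene correlation of 0.01. They were tested again with an estimated correlation, which leaves 1 degree of freedom. Hardly any list can pass that version after adjustment, so not passing it is no evidence against a shift. The list calls rest on the preset correlation. Each list's median was also placed among 10000 random lists matched on expression. Where a gene was not well above background on either array of a genotype, its fold is given as at least the bright group's mean over the higher of the lowest signal well above background and the gene's own, on log2 single-channel levels after loess and Aquantile.

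The 28 gene lists, their tests, the alternatives below and the rule for naming genes were fixed before the data were examined. The count of probes that name no locus, the split of the clock list, the gene families, and the further gene sets and explanations tested in the closing part were added later. The limits for calling a correlation moved (0.1) or a list outside random lists (percentiles 2.5 and 97.5) were set later. The rule takes both targets, the 15 genes highest and 15 lowest by mean log2 ratio past the threshold with the same sign on both arrays, and up to 4 members of each list with the smallest p (up to 8 for the iron, copper, cytochrome c oxidase and mitochondrial dysfunction lists). Other genes named were chosen after their values were seen. The alternatives were other background corrections, median centring, other filters, another variance model, the brightest probe, single-channel values without the array as a block, the deposited ratios, other thresholds and leaving out each array. The gene test was tried on simulated data of 20577 genes on 2 arrays, with 50 genes changed at each size, far fewer than were called in the data. It recovered 26% of genes changed by 0.3 on the log2 scale, 92% at 0.5, 100% at 1 and 100% at 2, with 9 false calls among 168. The list test found simulated lists shifted by 0.3 in 100 of 100 draws and called unshifted lists in 1 of 100. The simulated noise had the same SD for all genes and no correlation between genes. These results therefore do not measure errors where genes differ in spread or move together. Array number limits the precision. Plots were drawn with matplotlib 3.10.9.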

Results

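Transcript levels in shoots of an Arabidopsis line silenced for COX19 were compared with wild type on 2 dye-swapped arrays, with 1 silenced and 1 control sample on each (n = 2 per genotype). COX19 is known as a copper-binding protein needed for the assembly of cytochrome c oxidase in mitochondria. The comparison asks which transcripts differ between this line, in which an artificial microRNA targets COX19-1 and COX19-2, and wild type. Only 1 silenced line was measured, so effects of silencing cannot be told apart from other differences of the line. Between 73.7% and 75.0% of probes were well above background in each sample. All values are log2 ratios of silenced over control, given as the mean of 2 arrays; the SE of a gene's mean was 0.10.

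Transcripts of COX19-2 were lower in silenced shoots but still measured there. The probe specific to COX19-2 (AT1G69750; chromosome 1, 26237274 to 26237333 in TAIR10) gave -0.72 ± 0.00 (SD, n = 2), or 60.6% of control, with limma adjusted p = 3.9e-12 after Benjamini-Hochberg adjustment. Of the probes that name both COX19-1 (AT1G66590) and COX19-2, the probe at 24841734 to 24841880 on chromosome 1 gave -0.87 ± 0.05 (54.7% of control) and that at 24842062 to 24842121 gave -0.82 ± 0.05 (56.6% of control). Their limma adjusted p-values over all probes were 3.75e-14 and 1.25e-12. The only probe of COX19-1 alone was not well above background in any sample, so COX19-1 could not be measured by itself.

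**Figure D1:**
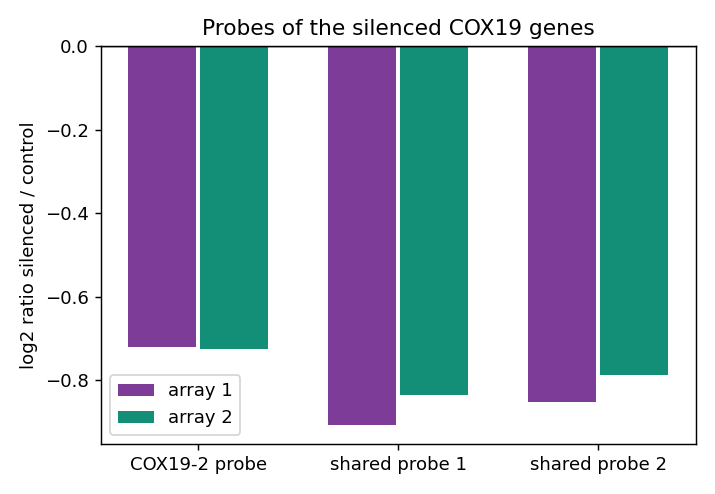
Log2 ratio of silenced over control for the 3 measured probes of the COX19 genes, with 1 bar per array. All 6 bars lie below 0, and the probe specific to COX19-2 stands at -0.72 on both arrays.

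Of 20577 genes tested with limma and Benjamini-Hochberg adjustment, 4116 were higher and 2664 lower in silenced shoots. By size, 557 genes were at least 2-fold higher on both arrays and 92 at least 2-fold lower, while 0 were beyond 2-fold with opposite signs; with the scanner's processed signals, 829 were at least 2-fold higher and 277 at least 2-fold lower. Across genes, which are not independent replicates, the arrays' ratios correlated with Pearson's r = 0.906 and Spearman's rho = 0.748. The direction of the balance depends on the scaling: 60.7% of calls were higher after loess, against 48.2% after median centring (2361 higher and 2537 lower) and 47.0% with the scanner's processed signals (3092 higher and 3492 lower). Because the test uses a common SD, 32 genes with opposite signs on the 2 arrays also passed it.

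The highest gene was NATA1, an N-acetyltransferase gene, at 5.93 ± 0.30 (SD, n = 2), 60.9-fold. It was followed by AT4G33720, described as a pathogenesis-related protein, at 5.40 ± 0.61, AT2G14247 at 5.22 ± 0.41, the transporter gene ABCG40 at 5.13 ± 0.15, the dirigent-like DIR5 at 5.11 ± 0.42 and the carboxypeptidase-like scpl30 at 5.09 ± 0.17. Germin-like genes AT5G39180, AT5G39120 and AT5G39110 were at 4.90 ± 0.38, 4.59 ± 0.25 and 4.08 ± 0.51, and peroxidase genes AT1G49570 and AT5G19890 at 4.37 ± 0.27 and 4.17 ± 0.44. The remaining genes among the 15 highest, BHLH100, IMA1, IMA2 and PR1, belong to lists given further on. All 15 had a limma adjusted p below what the software can represent.

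The lowest gene was QQS, a regulator of starch content, at -4.28 ± 0.10 (SD, n = 2). The dicarboxylate carrier gene DIC2 followed at -2.39 ± 0.05. Lipid-transfer-like genes AT4G12490, AT4G12500 and AT4G22470 were at -2.26 ± 0.23, -2.06 ± 0.36 and -2.05 ± 0.10, and AT3G09870, described as SAUR-like, was at -2.18 ± 0.03. AT1G07135 was at -2.09 ± 0.26 and AT5G44585 at -1.90 ± 0.09. Ethylene response factor genes ERF105, AT1G77640 and AT1G36060 were at -2.02 ± 0.02, -2.02 ± 0.17 and -1.76 ± 0.03. FLC, a repressor of flowering, was at -1.84 ± 0.14, PHI-1 at -1.84 ± 0.04, TCH4 at -1.79 ± 0.07 and MLO12 at -1.76 ± 0.04. The largest limma adjusted p among these 15 genes was 3.05e-68.

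**Figure D2:**
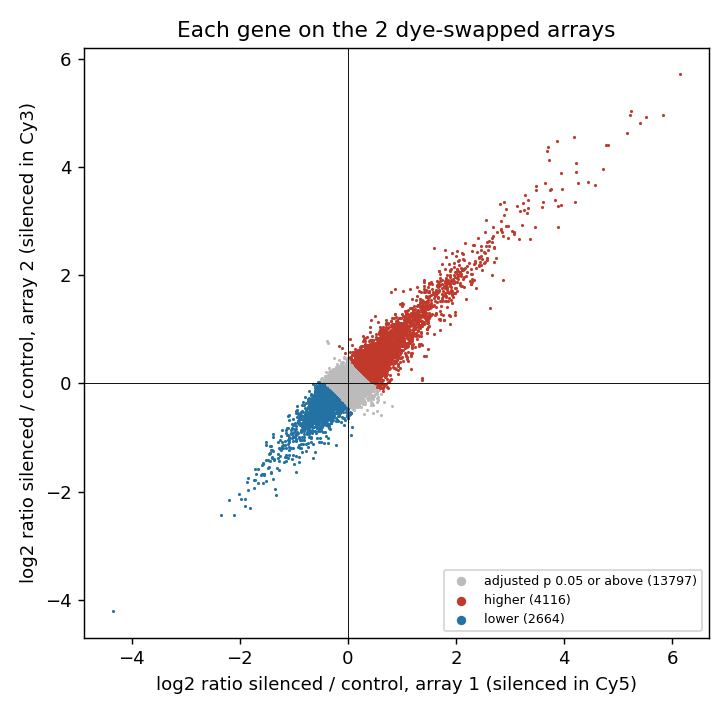
Log2 ratio of silenced over control for each of 20577 genes, array 1 on the x axis and array 2 on the y axis, with 4116 genes past the threshold and higher in red and 2664 lower in blue. Points follow the diagonal, with Pearson's r = 0.906 across genes.

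Most measured genes of the iron deficiency response rose, and the ferritin genes FER1, FER3 and FER4 fell. Of 29 measured iron deficiency genes, 20 rose and 3 fell (21 and 3 when adjusted over the list alone), with a median of 0.60. The bHLH regulator genes BHLH100, bHLH38, bHLH39 and BHLH101 were at 4.61 ± 0.28, 3.43 ± 0.22, 2.53 ± 0.09 and 2.42 ± 0.21 (SD, n = 2). The peptide genes IMA1, IMA2 and IMA3 were at 4.35 ± 0.53, 4.12 ± 0.64 and 3.78 ± 0.60, and NAS4, for nicotianamine synthesis, was at 2.06 ± 0.31. IMA1 and IMA2 are related copies, whose probes may share signal. The members that fell were NAS1 at -0.95, the root ferric reductase gene FRO2 at -0.44 and the iron transporter gene IRT1 at -0.29. Another 6 did not pass, among them the transcription factor gene FRU (FIT) at -0.06. The list passed camera with limma adjusted p = 9.79e-34. With an estimated correlation its camera adjusted p was 0.445, but on 1 degree of freedom hardly any list could pass that version, here and below.

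Of 10 measured genes of iron storage and iron excess, 2 rose and 5 fell (2 and 5 when adjusted over the list alone), with a median of -0.36. Ferritin genes FER1, FER4 and FER3 were at -0.66 ± 0.02, -0.56 ± 0.04 and -0.56 ± 0.01 (SD, n = 2). NAS3, for nicotianamine synthesis, was at -0.65 ± 0.11 and the metal transport gene YSL1 at -0.59 ± 0.08. VTL5 and VTL1 rose, at 0.30 and 0.25, while NEET, at -0.15, and the ferritin gene FER2, at 0.09, did not pass. The list as a whole did not pass camera (limma adjusted p = 0.0539), but passed in 4 of the other settings (limma adjusted p from 0.031 to 0.0496).

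Few copper deficiency genes differed. Of 11 measured, 2 rose and 1 fell (2 and 1 when adjusted over the list alone): FRO5 at 1.08 ± 0.18, the copper chaperone gene CCH at 0.46 ± 0.09 and ZIP2 at -0.41 ± 0.05 (SD, n = 2). FRO4 at -0.21, FSD1 at -0.16, COPT1 at -0.10, YSL2 at 0.09 and the regulator gene SPL7 at -0.09 did not pass. The list's median was -0.03 (0.01 with the deposited ratios and on array 1 alone) and its mean 0.06, the test leaned lower, and it did not pass camera (limma adjusted p = 0.962). Of 18 genes of copper proteins and copper delivery, 8 rose and 1 fell (8 and 1 when adjusted over the list alone), with a median of 0.08 (0.18 and 0.039 on the arrays). The copper pump gene HMA5 was at 1.06 ± 0.02, LAC3 at 0.91 ± 0.30, ARPN at 0.84 ± 0.12, LAC12 at 0.69 ± 0.09, MT2B at 0.58 ± 0.45, CSD1 at 0.46 ± 0.10 and AT1G66240 (ATX1) at 0.38 ± 0.15, while AT5G21930 (PAA2) fell, at -0.27 ± 0.16. This list did not pass camera (limma adjusted p = 0.17).

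Of 8 zinc deficiency genes, 4 rose and 1 fell (4 and 1 when adjusted over the list alone), with a median of 0.19, which was -0.06 without the filter on dim probes: NAS4, which is also in the iron list, HMA2 at 0.97, ZIP11 at 0.58 and ZIP1 rose, and ZIP5 fell, at -1.17. Of 12 phosphate starvation genes, 4 rose and 1 fell (4 and 1 when adjusted over the list alone), with a median of 0.12 (0.22 and 0.035 on the arrays); AT1G73010 (PS2) was at 1.64, PAP17 at 0.96, MGDC (MGD3) at 0.34 and PHT1;4 at -0.34. Neither list passed camera (limma adjusted p = 0.176 and 0.17).

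Several genes of cytochrome c oxidase and cytochrome c rose by small amounts. Of 10 measured subunit and cytochrome c genes, 6 rose and 0 fell (7 and 0 when adjusted over the list alone), with a median of 0.33. The cytochrome c genes CYTC-2 and CYTC-1 were at 0.52 ± 0.08 and 0.46 ± 0.10, COX5C-2, COX5C-3 and COX5C-1 at 0.43 ± 0.04, 0.40 ± 0.13 and 0.37 ± 0.08, and COX6B-2 at 0.29 ± 0.23 (SD, n = 2). COX6A at 0.22 and COX6B at 0.17 did not pass. Of 12 assembly genes, 2 rose and 0 fell (2 and 0 when adjusted over the list alone), with a median of 0.16: the copper chaperone genes COX17 at 0.64 ± 0.08 and COX17-2 at 0.46 ± 0.04. HCC1, HCC2 and SURF1B, each at 0.21, Erv1 at 0.17, COX11 at 0.15 and COX15 at 0.11 did not pass. Of 22 genes of other respiratory complexes, 4 rose and 0 fell (4 and 0 when adjusted over the list alone), with a median of 0.12, which was -0.0067 after median centring: TYKY-2 at 0.43, SDH1-1 at 0.34, ATP2b at 0.27 and SDH2-1 at 0.27. None of the 3 lists passed camera (limma adjusted p = 0.176, 0.456 and 0.688), but the subunit list passed in 4 of the other settings (limma adjusted p from 0.0104 to 0.0336).

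Genes known to respond to mitochondrial dysfunction rose together. Of 22 measured, 15 rose and 1 fell (16 and 1 when adjusted over the list alone), with a median of 0.42. The alternative oxidase gene AOX1D was at 2.84 ± 0.00 and AT12CYS-2 at 1.43 ± 0.06 (SD, n = 2). UPOX was at 1.24 ± 0.18, GSTU24 at 1.21 ± 0.04, DTX4 at 1.04 ± 0.03, CYP81D8 at 0.65 ± 0.14, and the alternative dehydrogenase genes NDB2 and NDA2 at 0.98 ± 0.04 and 0.70 ± 0.01. AOX1A, the best known alternative oxidase gene, was at 0.16 and did not pass, and TIM17-1 fell, at -0.39. The list passed camera with limma adjusted p = 1.08e-06, but adjusted p = 0.502 with an estimated correlation.

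Defence genes of both the salicylic acid and the jasmonate lists rose. Of 21 salicylic acid and pathogen defence genes, 17 rose and 1 fell (17 and 1 when adjusted over the list alone), with a median of 1.24. PR1 was at 4.15 ± 0.10, PAD3, for camalexin synthesis, at 3.93 ± 0.29, BGL2 (PR2) at 3.07 ± 0.20 and FMO1 at 2.08 ± 0.30 (SD, n = 2), and CBP60G fell, at -0.54. Of 18 jasmonate and wound genes, 17 rose and 0 fell (17 and 0 when adjusted over the list alone), with a median of 1.40. The defensin genes PDF1.2 and PDF1.2b, near-identical copies whose probes may share signal, were at 3.58 ± 0.42 and 3.53 ± 0.06, TAT3 at 3.28 ± 0.08 and VSP2 at 2.92 ± 0.16. The lists passed camera with limma adjusted p = 1.91e-32 and 4.28e-41, but each had adjusted p = 0.445 with an estimated correlation.

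All 10 hypoxia genes rose (10 when adjusted over the list alone), with a median of 2.00. ADH1, for ethanol fermentation, was at 2.91 ± 0.23, the oxygen-sensing oxidase gene PCO2 at 2.37 ± 0.21, SUS4 at 2.15 ± 0.03 and the haemoglobin gene HB1 at 2.13 ± 0.02 (SD, n = 2). Camera called the list with limma adjusted p = 1.03e-31, but adjusted p = 0.583 with an estimated correlation.

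Genes of flavonoid and anthocyanin synthesis rose as well. Of 15 measured, 12 rose and 0 fell (13 and 0 when adjusted over the list alone), with a median of 0.91. DFR was at 2.82 ± 0.04, AT1G56650 (PAP1), a regulator of anthocyanin genes, at 2.38 ± 0.05, GSTF12 (TT19) at 2.13 ± 0.10 and UF3GT at 1.86 ± 0.03 (SD, n = 2). The list passed camera with limma adjusted p = 1.2e-18, but adjusted p = 0.445 with an estimated correlation. Of 18 glucosinolate genes, 11 rose and 2 fell (11 and 2 when adjusted over the list alone), with a median of 0.40. IMS2 (MAM3) was at 2.06 ± 0.03, CYP79B2 at 1.37 ± 0.05 and CYP83B1 at 0.84 ± 0.23, while CYP79F1 fell, at -0.94 ± 0.47. This list passed camera with limma adjusted p = 0.00788, but adjusted p = 0.609 with an estimated correlation.

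Cell cycle genes rose by smaller amounts. Of 19 measured, 16 rose and 0 fell (16 and 0 when adjusted over the list alone), with a median of 0.48. CYCA1;1 was at 1.18 ± 0.21, CDKB1;1 at 0.94 ± 0.03, CYCB1;4 at 0.82 ± 0.15 and the cytokinesis gene SYP111 (KNOLLE) at 0.81 ± 0.20 (SD, n = 2). As a group they passed camera with limma adjusted p = 0.000193, but adjusted p = 0.583 with an estimated correlation. Of 8 wall loosening genes, 3 rose and 4 fell (3 and 4 when adjusted over the list alone), with a median of -0.15; XTH15 was at -0.73, XTH4 at -0.63, EXPA11 at -0.52 and EXPA10 at 0.47. This list did not pass camera (limma adjusted p = 0.296).

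Photosynthesis genes encoded in the nucleus showed no common shift. Of 45 measured, 9 rose and 2 fell (9 and 2 when adjusted over the list alone), with a median of 0.03, which was -0.10 after median centring and -0.06 on array 2 alone. LHCB2.3 was at 0.91 ± 0.08, LHCB4.3 at 0.79 ± 0.04 and LHCB2.2 at 0.65 ± 0.25 (SD, n = 2). CAB2 passed at a mean of 0.71 although its arrays gave 1.37 and 0.06, and it did not pass with an intensity trend in the variance (adjusted p = 0.159). LHCB genes are similar copies whose probes may share signal. Of 14 chlorophyll and haem synthesis genes, 0 rose and 5 fell (0 and 8 when adjusted over the list alone), with a median of -0.22 (-0.28 and -0.12 on the arrays); PORA was at -0.71, PORB at -0.44, ALB1 (CHLD) at -0.35 and HEMA1 at -0.28. Neither list passed camera (limma adjusted p = 0.688 and 0.0539), and the second passed in 5 of the other settings, with limma adjusted p = 0.00502 after median centring, 0.00774 without the replicate block, 0.0119 with the deposited ratios, 0.0163 with offset 10 and 0.0349 with the processed signals.

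Rapid touch and handling genes fell. Of 11 measured, 0 rose and 9 fell (0 and 9 when adjusted over the list alone), with a median of -0.75: ERF105 is given above, TCH4, a wall enzyme gene, was at -1.79, ERF104 at -1.63 ± 0.10 and ERF5 at -1.32 ± 0.09 (SD, n = 2). The list passed camera with limma adjusted p = 1.78e-10, but adjusted p = 0.493 with an estimated correlation. Of 20 drought, cold and abscisic acid genes, 2 rose and 8 fell (2 and 8 when adjusted over the list alone), with a median of -0.09. CBF2 and CBF1 were at -1.33 ± 0.27 and -1.30 ± 0.20, with CBF1 well above background on 1 of 2 arrays in silenced shoots, AT5G66400 (RAB18) was at -1.17 ± 0.22, and LTI30 rose, at 1.25 ± 0.22. This list passed camera with limma adjusted p = 0.033, but adjusted p = 0.583 with an estimated correlation. It also did not pass with the processed signals (limma adjusted p = 0.0965), after median centring (0.0843), with probes bright in all 4 channels (0.111) or without the replicate block (0.057).

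Clock genes moved both ways. Of 14 measured, 4 rose and 6 fell (6 and 6 when adjusted over the list alone): the morning genes LHY at 0.62 ± 0.06 and CCA1 at 0.54 ± 0.03 rose, and the evening genes PCL1 (LUX) at -0.57 ± 0.06 and PRR5 at -0.56 ± 0.20 fell (SD, n = 2). Of the 7 morning genes 4 rose and 0 fell, and of the 7 evening genes 0 rose and 6 fell; the morning median exceeded the evening median by 0.72, with 0.61 and 0.75 on the arrays, a split made after the data were seen. Over the whole list, where the opposite changes offset each other, the median was 0.09 (-0.0088 after median centring) and the mean 0.01, and camera, which leaned lower, did not pass it (limma adjusted p = 0.688). These genes follow the time of day, and they moved in the same samples as every other group given here.

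Of 15 root tissue markers, 9 rose and 0 fell (9 and 2 when adjusted over the list alone), with a median of 0.30; BGLU22 was at 2.23 ± 0.00, THAS1 at 1.77 ± 0.14, BGLU21 at 0.78 ± 0.00 and NRT2:1 at 0.62 ± 0.11 (SD, n = 2), the last well above background on 1 of 2 arrays in control shoots. The list passed camera with limma adjusted p = 0.00282, but adjusted p = 0.583 with an estimated correlation. Of 3 measured seed and embryo markers, 0 rose and 2 fell (0 and 3 when adjusted over the list alone), with a median of -0.31: GEA6 (EM6) was at -1.12 ± 0.07, EM1, not well above background in silenced shoots, was at least 1.24-fold lower, and OLEO2 did not pass. This list passed camera with limma adjusted p = 0.0336, but adjusted p = 0.583 with an estimated correlation. It did not pass after median centring (limma adjusted p = 0.137) or without the filter on dim probes (0.249), where its median was 0.037.

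The remaining lists did not pass camera in the main setting. Of 9 antioxidant genes, 3 rose and 2 fell (4 and 2 when adjusted over the list alone), with a median of 0.08 (0.19 and 0.021 on the arrays, and -0.07 after median centring), a mean of -0.01 and a test that leaned lower (limma adjusted p = 0.688); STZ (ZAT10) was at -1.07, RHL41 (ZAT12) at 0.46, MSD1 at 0.31 and the catalase gene AT4G35090 (CAT2) at -0.29. Of 9 senescence genes, 4 rose and 0 fell (5 and 1 when adjusted over the list alone), with a median of 0.23 (limma adjusted p = 0.052, and 0.0348 without the filter on dim probes); SAG13 was at 2.94, AT4G35770 (SEN1) at 0.35, NYE1 at 0.32 and NAC6 (ORE1) at 0.25. Of 8 heat shock genes, 3 rose and 0 fell (3 and 0 when adjusted over the list alone), with a median of 0.14, or 0.27 and 0.087 on the arrays (limma adjusted p = 0.68); HSFA2 was at 0.51, MBF1C at 0.32 and HSP18.2, which did not pass, at 0.14, and HSP17.4, not well above background in control shoots, was at least 1.27-fold higher.

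**Figure D3:**
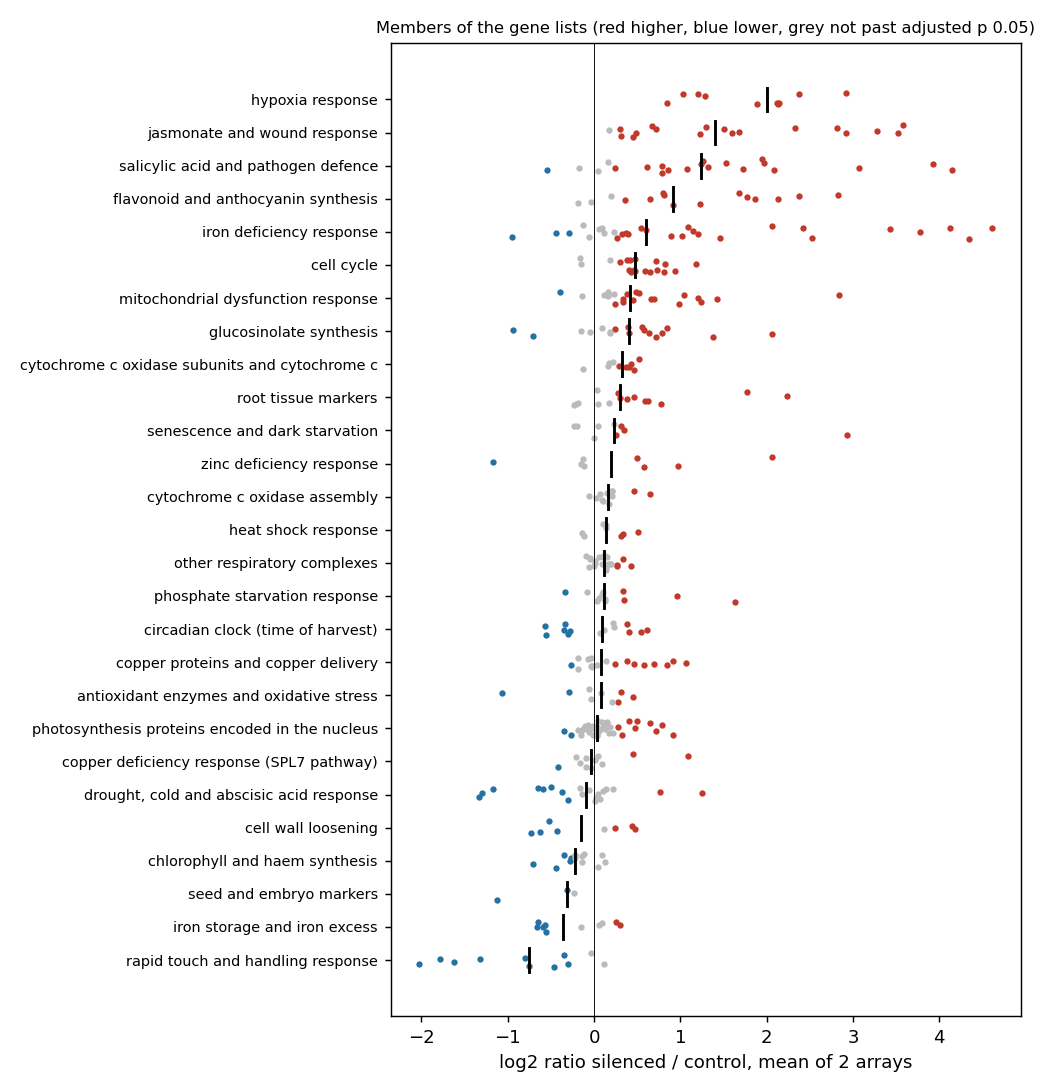
Log2 ratio of silenced over control (x axis, mean of 2 arrays) for each measured member of the 27 tested gene lists, with 1 list per line and a black bar at its median. The hypoxia list has the highest median, at 2.00, and the touch and handling list the lowest, at -0.75.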

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

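The count of probes that name no locus and the split of the clock list were chosen after the ratios had been seen. So was the test of a construct carrying part of the miR319a precursor. The other tests given here were written before their results were seen, but the bound met against less handling was set aside afterwards.

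Probes that name no locus also gave signals: of 2938 tested, 38 were at least 2-fold higher on both arrays and 6 at least 2-fold lower, and 0 had opposite signs. Probe A_84_P761415 (chromosome 3, 14749677 to 14749736 in TAIR10) was not well above background in silenced shoots and was at least 10.02-fold lower there. Probe A_84_P796276 (chromosome 1, 24082576 to 24082635), well above background on 1 of 2 arrays in silenced shoots, was at -2.88.

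The highest of all tested probes was A_84_P764708, which the array describes as a miR319a precursor (chromosome 4, 12352983 to 12353042), at 6.62 on the log2 scale, with 7.53 and 5.72 on the 2 arrays. If the plant's own MIR319a gene gave more mature miR319, its TCP and MYB targets should be lower. The 7 measured targets had a median of -0.091, with -0.12 and -0.065 on the arrays. That median and array 2 lay past the bound set against this, but array 1 fell short of it. Neither array reached the bound set for it, and TCP4 alone passed, at -0.45 (limma adjusted p = 3.42e-05). The other candidate explanation is a silencing construct that carries part of this precursor, a common backbone of artificial microRNAs, which predicts targets that are not lower. Each bound had to be met on both arrays, and array 1, at -0.12, met none of them, so both explanations stay open. The construct's sequence was not analysed here.

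The fall of rapid touch and handling genes (median -0.75) may reflect the time of harvest or less handling of the silenced plants. Within the clock list, morning genes exceeded evening genes by 0.72 in median. Further genes taken as morning-phased exceeded those taken as evening-phased in the same direction by 0.40, with 0.22 and 0.37 on the arrays. Array 1 missed the bound set for a difference in time of harvest, and both arrays were above the bound set against it. The evening set was mixed: of 11 genes, GRP7, PRR3 and AT5G08330 fell, at -0.65, -0.53 and -0.44, and STH rose, at 0.63. Its median was the value of ZTL, and on array 1 that of LKP2. Whether each member peaks in the evening was not checked, so the miss on array 1 decides little. A second set of 21 rapid wound and handling genes had a median of 0.019, which met the bound set against less handling. Yet 6 of them rose and 9 fell, with an SD of 0.79 among members. The set's median also lay within that SD of the touch list's median, though only just. For these reasons the met bound was not taken as a verdict. This step was decided after the result was seen and was not applied to the other tests. An SD among members is also not the error of a median. Taken as written, the bound counts against less handling. The jasmonate and wound list did not fall either, with 17 of 18 genes higher. The time of harvest stays open, and less handling does so only with its bound set aside. A difference due to silencing was not tested apart from them and stays open too.

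Root markers rose in samples labelled as shoots, and root material in the silenced samples could account for this. A further 20 root genes had a median of 0.10, with 0.18 and 0.03 on the arrays, short of the bound set for root material; the bound set against it was not met either, since array 1 lay above it and 6 of the genes rose (30.0%). CYP86A1, GPAT5 and RWP1 rose, at 0.97, 0.72 and 0.77, while SKOR and MLP34 fell, at -0.42 and -0.45. All 20 were measured in these leaves, and PYK10, abundant in roots, was at 0.59. Root material therefore stays open, and so does a change of these genes in leaves.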

How the results depend on the processing

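The count of unnamed probes was chosen after seeing the data; every other alternative was set beforehand, but the limits 2.5 and 97.5 for percentiles and 0.1 for a correlation were set later. With 2 arrays a mean cannot differ from either array by 1 SD, so leaving out an array tests single genes weakly. Signal over background limits the dim genes. COX19-2 stayed between -0.87 and -0.72 and the shared probes between -1.02 and -0.81, all past the threshold, in every setting with a test. No target, and no called gene among the 159 taken by the naming rule, turned direction; single values of genes named outside the rule were not recomputed. The balance of higher over lower calls did turn, with median centring and with processed signals.

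Median centring gave 2361 genes higher, against 4116, and a test against 1.2-fold gave 1743 higher and 593 lower. Without the replicate block, 4664 genes were higher and 3342 lower. The scanner's processed signals gave 277 genes 2-fold lower on both arrays, against 92. At 1.5-fold, 1227 were higher and 325 lower, and at 3-fold 252 and 20; among unnamed probes, 38 and 6. Spearman's rho fell to 0.64 with no filter.

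With an estimated correlation, on 1 degree of freedom, 0 of the 12 called lists passed. The smallest unadjusted camera p was 0.0429, for jasmonate. Hardly any list could pass on so few degrees of freedom, so these failures do not argue against a shift. The camera adjusted p was 0.445 for iron deficiency, salicylic acid, jasmonate and flavonoid, 0.493 for touch, 0.502 for mitochondrial dysfunction, 0.583 for cell cycle, drought, hypoxia, root and seed, and 0.609 for glucosinolate. Among random lists, percentiles were 0 for iron storage, 0.12 for chlorophyll, 97.52 for oxidase assembly, 99.9 for oxidase subunits and 98.3 for senescence, outside those limits, and 4.04 for drought, within them.

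Some list calls changed, and the cause was not tested. Oxidase subunits passed with processed signals (median 0.31), offset 10 (0.33), deposited ratios (0.32) and no replicate block (0.33). Chlorophyll passed with processed signals (-0.26), offset 10 (-0.22), median centring (-0.35), deposited ratios (-0.21) and no replicate block (-0.22). Iron storage passed with offset 10 (-0.36), no filter (-0.28), the brightest probe (-0.32) and deposited ratios (-0.35), and senescence with no filter (0.14). Drought was lost with processed signals (-0.18), median centring (-0.17), probes bright in all 4 channels (-0.054) and no replicate block (-0.094). Seed was lost with median centring (-0.18) and no filter (0.037, a median of the other sign, with the test still leaning lower), and had too few members with probes bright in all 4 channels.

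Leaving out each array gave medians of 0.57 to 0.77 for iron deficiency, -0.35 to -0.33 for iron storage, 0.12 to 0.15 for oxidase assembly, 1.18 to 1.23 for salicylic acid, 1.40 to 1.41 for jasmonate, -0.10 to -0.070 for drought, 0.080 to 0.081 for clock, 0.30 to 0.33 for root, 0.19 to 0.25 for zinc, 0.40 to 0.42 for mitochondrial dysfunction, 0.087 to 0.27 for heat shock and -0.76 to -0.67 for touch. Lists that were not called moved by more than 1.5 times for phosphate (0.035 to 0.22), copper proteins (0.039 to 0.18), antioxidants (0.021 to 0.19), chlorophyll (-0.28 to -0.12), copper deficiency (-0.069 to 0.010) and photosynthesis (-0.06 to 0.19), as did heat shock. Medians of lists that were not called changed sign for other respiratory complexes, antioxidants, photosynthesis and clock after median centring, zinc with no filter, copper deficiency with deposited ratios or without replicate 2, and photosynthesis without replicate 1. For the 159 genes of the naming rule, 43 of 1903 values lost their call and 16 gained one. The 2-fold counts and correlations do not use the variance model and have no value without the replicate block.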

Other observations

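The gene families in the first paragraph were chosen after the results had been seen; the test of the wider hypoxia set was written before its result was seen.

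Families linked to defence and detoxification held more calls than the array as a whole, where 4116 of 20577 genes were higher and 2664 lower; the excess was not tested. Of 22 germin-like genes, 16 were higher and 1 lower by limma, with a median of 0.50. The probes of AT5G39180, AT5G39120 and AT5G39110 shared runs of at most 6 bases. They were compared with each other only, not with the other genes' transcripts, so shared signal stays possible. Of 55 glutathione S-transferase genes, 32 were higher and 2 lower (median 0.39), and of 86 peroxidase genes, 42 were higher and 13 lower (median 0.23). Of 65 WRKY genes, 24 were higher and 12 lower (median 0.17), and of 165 cytochrome P450 genes, 67 were higher and 28 lower (median 0.07). Of 93 UDP-glycosyltransferase genes, 36 were higher and 12 lower (median 0.11). Ribosomal protein genes, by contrast, had 47 higher and 11 lower of 350 (median 0.06, which was -0.06 after median centring). The other medians stayed above 0 with the processed signals and after median centring.

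A hypothesis from the hypoxia list was that a wider set of hypoxia genes would be higher too. Of 20 further genes, none in the fixed lists, 14 rose and 4 fell, with a median of 0.68 (0.73 and 0.55 on the arrays), which met the bound set in advance. The wound-responsive gene AT4G10270 was at 2.47, ACO1 at 1.84 and AT1G19530 at 1.83, and AT3G23170 fell, at -0.95. The result is consistent with a shift of hypoxia genes beyond the list, but many of these genes also respond to wounding or defence, and oxygen was not measured.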
